A study of Mus musculus with 10 samples.

How the data were processed

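The samples were 5 IP and 5 input libraries of m6A-seq from C57BL/6J mouse cortex, 1 of each for sham and for 1, 3, 5 and 7 days after traumatic brain injury. Per the labels' protocols, total RNA was taken from injured cortex with Trizol and fragmented chemically, fragments bound by anti-m6A beads were eluted, and IP and input fragments were made into strand-specific dUTP libraries that were read as pairs on an Illumina NovaSeq. The series' design text says that the cortex was minced and dissociated with enzymes, and the labels call the source a brain cell. Whether cell types were sorted is not given in the sources used here, so the share of each cell type in the RNA is unknown. The submitters' processing notes name HISAT2, StringTie and HOMER and the build GRCm38 (mm10), with no versions and no roles. The peak caller, its settings and the annotation are not given in the sources used here.

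The values used were those of the 5 peak lists that the authors deposited, each holding the peaks of 1 IP library over its own input, per the file headers, so peaks were called per library and never on pooled samples. The authors gave each peak a p-value, its log10, the log10 of an FDR, a fold enrichment of IP over input (a linear ratio), the blocks of exon sequence it covers, a gene name and an annotated region (5' UTR, 3' UTR or other exon), per the file headers. How the authors normalized the fold or the p-value is not given in the sources used here, and both depend on depth. With 2 exceptions they were used to describe, rank or filter peaks within a list and are set side by side as the authors' values. The fold was averaged over the 4 injured lists to rank genes gained at all 4 days. The -log10 p was averaged over the 5 lists to set the classes of peak strength of the random gene lists. The highest p in any list was 0.05. The number of reads, the depth of each library and the input levels were not analysed here.

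Between 23 and 27 peaks per list repeated the coordinates of another peak and were counted once. A gene counted as having a peak where at least 1 peak bore its name. A pair of peaks counted as shared where the bases common to their exon blocks came to at least 50% of the shorter peak. The planned rule used the strand where the files give it. The strand in the files was that of the annotated gene and not of the peak, so strand was left out and used as an added alternative. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per group no test between groups was made, and the number of genes that 4 libraries have and 1 lacks was computed with each library in the place of sham. Gene names are those of the files: of 17894 names, 16394 are symbols of the RefSeq gene table used here, and 16453 with synonyms.

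Strong peaks are those at an FDR of at most 0.001. For 25 gene lists, with 418 distinct genes of which 363 had a peak, the number of members with a peak was compared with sham, and the net gain was placed among 10000 random lists with as many genes in each of 10 classes of peak strength (the mean over the 5 lists of -log10 p of the gene's best peak, at most 320, and 0 without a peak). The 10 classes and the random seed 1 were fixed in the code. Members with no peak in any library were left out of each list, so a member listed in a single library entered through that library. Random lists were drawn from genes with a peak in the same way. A list with fewer than 2 members with a peak got no percentile. Random lists with the same net gain were split evenly between those below and those above. A list is called above the central 95%, or the random range, at a percentile of at least 97.5. A net gain that only equals the 97.5th percentile value of random lists can thus count as above. A percentile describes these libraries and is no test, since genes are not replicates. About 0.6 of the 24 lists with a percentile would lie above, and as many below, the central 95% at each day by chance. The lists overlap slightly, such as Lcn2 on the reactive astrocyte and neutrophil lists and Hspb1 on the reactive astrocyte and heat shock lists. Pathway names in the files were tested for at least 10 genes with a strong peak in the same way.

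The groups, the comparisons, the gene lists, most alternatives and the rule for the genes named were set before the data were examined. The rule named Socs3, Alkbh5 and the m6A writers, erasers and readers, then, since no reads were used, the 10 gained and 10 lost genes per day with the highest fold in the list that has them, the 10 gained at all 4 days with the highest mean fold, the 10 lost at all 4 with the highest sham fold, and 2 to 4 members of each described gene list in the order of that list. Predicted genes and clone names were left out, and some genes that the rule takes are not reported here. Members named beside the strong-peak counts of the 4 lists, and those named as gained or lost where 5 or fewer were, were chosen after their values were seen. Genes whose peak lay where the other list had a peak under another gene name (at least 1 base, any strand) were marked. Enrichment change at shared peaks and input level, which were planned, were not computed, because both need reads or input levels.

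Alternatives were an FDR of at most 0.001, a fold of at least 2, overlaps of 1 base or of 50% of both peaks, the same number of peaks from each library (30039, or 18083 strong peaks), each injured library left out in turn and, chosen after the data were seen, the strand of the annotated gene, no peak at the same place under another gene name, a strong peak against no peak at all, and the same number of strong peaks for the gene lists. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: each of the 3 overlap rules classed 100% of 4000 simulated peaks correctly, and of 200 simulated lists of 20 genes, 1.5% of those without planted gains and 100% of those with 6 lay above the central 95% of random lists.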

Results

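The data were m6A peak lists from mouse cerebral cortex after traumatic brain injury. N6-methyladenosine (m6A) is a methyl mark on adenosines of RNA, and in m6A-seq fragments carrying it are pulled down with an antibody and set against the unselected input RNA. C57BL/6J mice were sampled in a sham group and 1, 3, 5 and 7 days after injury. Each of the 5 groups had 1 immunoprecipitated (IP) library and 1 input library, 10 samples in all, and the authors' peak list of each IP library over its own input was the measurement used. Whether particular cells were selected from the tissue is not given in the sources used here. The series title names Alkbh5, an enzyme that removes m6A, and Socs3, a suppressor of cytokine signalling, in microglia and macrophages, and the time course asked which transcripts carried m6A at each time after injury. No group had a replicate, so no difference between conditions could be tested, and each count or value below describes 1 library. All 4 comparisons used the same sham library, so the 4 days are not independent repeats, and part of what they share may come from that library.

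The lists held 30573 peaks in sham, 30039 at day 1, 30135 at day 3, 32769 at day 5 and 31511 at day 7. These lay in 14696, 14473, 14604, 15408 and 14994 genes. The median fold enrichment of a peak over input, as the authors gave it, was 5.72 in sham, 5.46 at day 1, 5.87 at day 3, 5.27 at day 5 and 5.69 at day 7. All peaks had an authors' p of at most 0.05, and between 59.1% and 61.4% of a list passed an authors' false discovery rate (FDR) of at most 0.001. The latter are called strong peaks here. In every library the 3' UTR held the most peaks, 51.1% in sham (exact Clopper-Pearson 95% interval 50.5% to 51.6%), 51.3% at day 1, 51.6% at day 3, 50.6% at day 5 and 50.3% at day 7 (49.8% to 50.9%). Peaks in the 5' UTR made up 23.6% of the sham list and 23.3% to 24.6% of the injured lists. These intervals cover counting error only. The number of reads behind each library was not analysed here, so depth is unknown.

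Socs3 (ENSMUSG00000053113), which the study's title names, had an m6A peak in its 3' UTR in sham and at every day after injury. The strongest Socs3 peak by p in sham ran from 117966973 to 117967956 on chromosome 11 (GRCm38), on a minus-strand gene whose transcript spans 117966079 to 117969186. Its counterparts ran from 117966943 to 117968045 at day 1, 117967003 to 117968045 at day 3, 117966943 to 117968075 at day 5 and 117967062 to 117968135 at day 7. The authors' fold enrichment of this Socs3 peak was 27.6 in sham, 13.8 at day 1, 19.9 at day 3, 12.6 at day 5 and 10.6 at day 7, while the authors' log10 p was -7.25, -123, -37.4, -42.5 and -19.6. The sham list thus gave Socs3 the highest fold and the weakest p of the 5 lists. These values come from separate lists with unknown depth, and only the sham fold was a whole multiple, within rounding, of the smallest fold step of its list, 29 steps of 0.953. A second 3' UTR peak of Socs3 was listed in all 5 libraries, and day 1 had a further exon peak from 117969809 to 117969987 with a fold of 9.61.

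**Figure D1:**
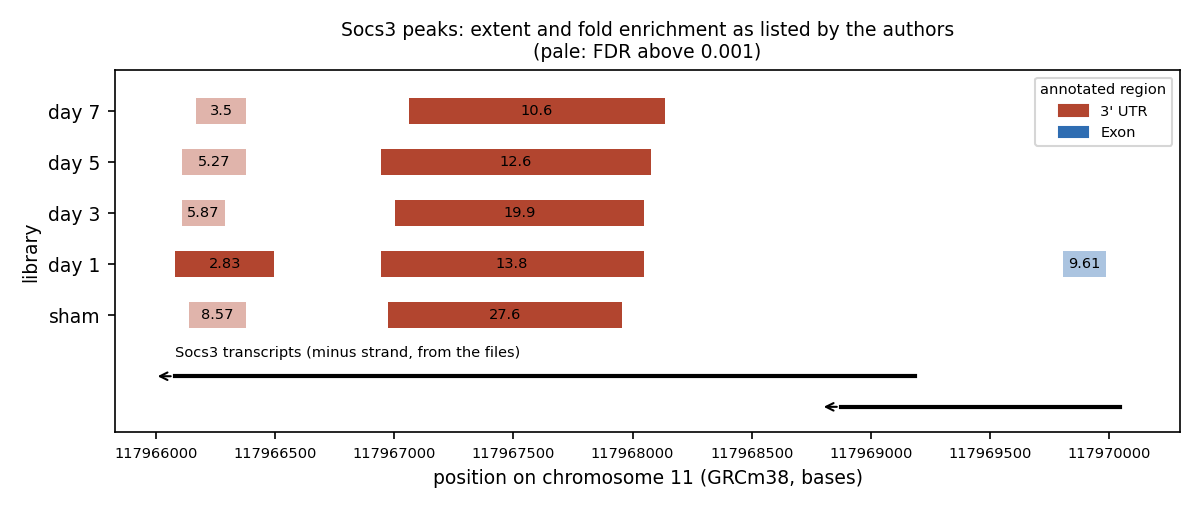
Socs3 peaks along chromosome 11 (GRCm38 position in bases) in each of the 5 libraries, coloured by annotated region, pale where the FDR is above 0.001 and numbered with the authors' fold, with 2 Socs3 transcripts drawn beneath. The broad 3' UTR peak is listed in all 5 libraries, with folds of 27.6 in sham and 10.6 to 19.9 after injury.

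Alkbh5 (ENSMUSG00000042650) had no strong peak in sham, at day 1 or at day 3 and 1 strong peak each at day 5 and day 7. The day 5 peak lay in the 3' UTR at 60557883 to 60558093 on chromosome 11, with a fold of 7.21 and a log10 p of -6.76 for Alkbh5. The day 7 peak lay in the 5' UTR at 60538170 to 60538439, with a fold of 3.68. The other libraries listed Alkbh5 peaks with a weaker p. The best of them by p had a fold of 10.5 in the 5' UTR in sham and 5.14 in the 5' UTR at day 3. At day 1 the best had a fold of 2.35 in the 3' UTR, from 60557913 to 60558093, within the place of the day 5 peak. By fold the sham peak was thus the highest of these. Fto, the other m6A demethylase, had a strong 5' UTR peak in all 5 libraries. Of 9 writer genes, which place m6A, 8 had a peak in sham, day 1, day 3 and day 7 and 9 at day 5, where Mettl3, the catalytic subunit, had a single weak exon peak with a fold of 4.83. Mettl14, the partner of Mettl3, had a strong 3' UTR peak in sham (fold 3.55), day 5 (3.22) and day 7 (3.32) and weaker peaks at day 1 and day 3. Of 9 reader genes with a peak in any library, 9 had one in sham, 8 at day 1 and day 3 and 7 at day 5 and day 7. Igf2bp3, a reader that binds methylated mRNA, was listed in sham alone, and Ythdc2, a reader with helicase activity, was without a listed peak at day 5. The Igf2bp3 peak had a log10 FDR of -1 and the Ythdc2 peaks had -0.49 to -1.22, so all were weak. Hnrnpc, the other reader missing at day 7, had a weak peak in sham and at day 3 and a strong one at day 1 and day 5. The strong Hnrnpc peaks lay in an exon with folds of only 1.3 and 1.28, and the weak ones in the 5' UTR with 1.85 and 2.32. The net losses of the readers lay within the central 95% of random lists at every day, with percentiles between 2.90 at day 5 and 20.6 at day 3, and with strong peaks the direction turned at day 1 and day 5, with 6 readers in sham and 7 at those days. Hnrnpc was the only reader gained in that turn.

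Most m6A peaks were listed at the same place in sham and after injury, and the overlap of sham with the injured libraries lay in the same range as that among the injured libraries. A sham peak overlapped 81.2% of the day 1 peaks (80.8% to 81.7%), 82.0% of the day 3 peaks, 76.4% of the day 5 peaks and 79.1% of the day 7 peaks, with an overlap of at least 50% of the shorter peak. Across the 12 ordered pairs of injured libraries the share ran from 76.2% to 84.7%, and across the 8 ordered pairs with sham from 76.4% to 83.1%. Genes with a listed peak after injury and none in sham are called gained, and those with a peak in sham and none after injury lost. There were 1315 gained and 1538 lost genes at day 1, 1331 and 1423 at day 3, 1862 and 1150 at day 5, and 1537 and 1239 at day 7. By construction gained minus lost genes equals the difference in genes with a peak between the injured list and sham. With strong peaks only, gained genes outnumbered lost ones at every day, because sham had the fewest genes with a strong peak (10922 against 10939 to 11580). The order at day 1 and day 3 thus turned, to 1000 gained and 983 lost and to 1065 and 806. At day 1 the order turned back, to 821 and 827, once genes with a strong peak at the same place under another name were left out, and with the same number of peaks from each library day 3 had 1382 of each and day 5 had 1544 gained and 1368 lost. Of 24 gene lists with at least 2 members with a peak, 2 lay above the central 95% of random lists at day 1, 2 at day 3, 3 at day 5 and 3 at day 7, where about 0.6 would by chance.

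**Figure D2:**
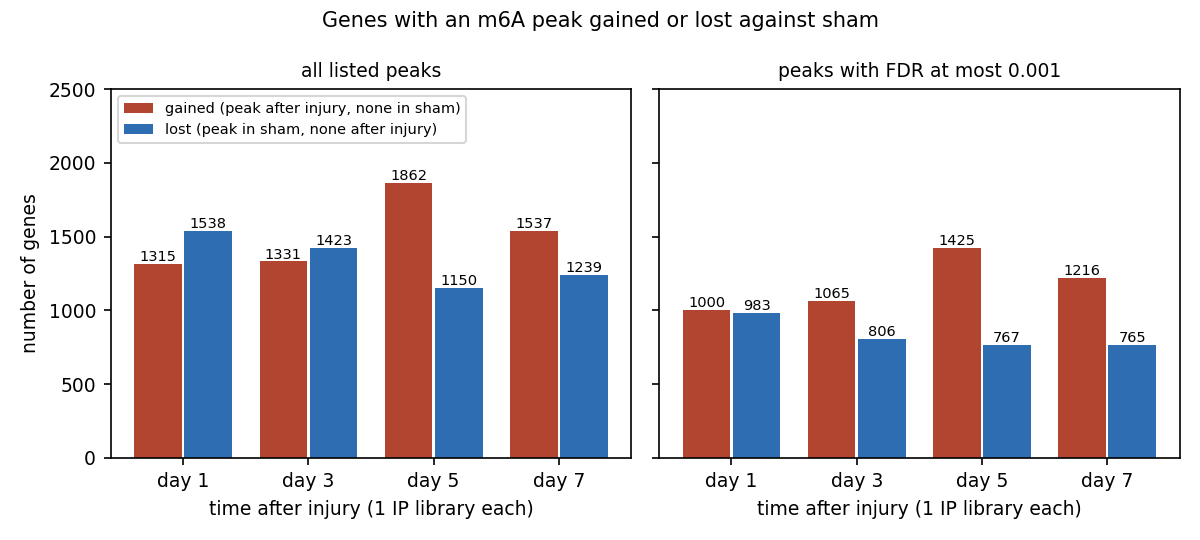
Number of genes (vertical axis) that gained or lost an m6A peak against sham at each day after injury, 1 IP library per day, for all listed peaks on the left and peaks at an FDR of at most 0.001 on the right. With all peaks, lost genes outnumber gained ones at day 1 (1538 against 1315) and day 3, and with strong peaks gained genes outnumber lost ones at all 4 days, most at day 5 (1425 against 767). Gained minus lost is by construction the difference in genes with a peak between that day's list and sham.

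At day 1 after injury, cytokine transcripts and reactive astrocyte transcripts gained m6A peaks that sham lacked. Of 15 cytokines and chemokines with a peak in any library, 7 gained one and 2 lost one, a net gain at the 99.4th percentile of 10000 random gene lists matched on peak strength. Among them were Il6, an acute-phase cytokine, with a fold of 2.77, Tnf, a proinflammatory cytokine, with 11.8, and Ccl3, a macrophage chemokine, with 2.22, none of which was a strong peak. Il1a and Ccl12 had weak peaks in sham, each with a fold of 6.67, and none at day 1. Of 17 reactive astrocyte genes 5 gained a peak and 0 lost one (99.9th percentile). Lcn2, a secreted lipocalin of acute inflammation that is also on the neutrophil list, had a fold of 13.3, Hspb1, a small heat shock protein, 3.33 and Cd44, a hyaluronan receptor, 2.98 with a log10 p of -29.4. Among 32 neuronal genes 0 gained and 2 lost a peak, Syt1, a calcium sensor of synaptic vesicles, with a fold of 7.62 in sham, and Nefl, a neurofilament subunit, with 9.53. That net loss lay at the 2.44th percentile, and with strong peaks it was 1 gene at the 18.4th. Hmox1, a haem-degrading enzyme induced by stress, gained a 3' UTR peak on chromosome 8 from 75100381 to 75100589 with a fold of 22.9. Gpr65, a proton-sensing receptor of immune cells, had a fold of 22.6, S100a7a 20, Acyp2 17.7, and Wdr70 led the gained genes with 35.5. Ccdc71, Tma7, Mir1964 and Kank4os were also among the 10 gained genes with the highest folds, but sham listed a peak at the same place under another gene name. Of the lost genes, Zxda, an X-linked zinc finger gene, had the highest fold in sham, 529, and is uncertain because it has a near-identical copy, Zxdb. Tom1, Sarnp, Myom3, Grk2, Olfr464, Alkbh3os1 and Pdgfd followed with sham folds between 20 and 36.2, and Pcdha7 and Pcdhga5, from clusters of overlapping protocadherin genes, lay at places that day 1 listed under another name.

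At day 3 the m6A peaks that sham lacked included those of phagocytic myeloid genes and of infiltrating monocytes and macrophages. Of 18 phagocytic or disease-associated myeloid genes with a peak in any library, 6 gained one and 2 lost one (97.9th percentile). Itgax, an integrin of dendritic cells and activated microglia, had a fold of 7.34, Spp1, which encodes osteopontin, 2.93 with a log10 p of -16.1, and Clec7a, a receptor for fungal glucans, 3.16. The lost members were Trem2, a lipid receptor of microglia, and Gpnmb, a glycoprotein of phagocytes, both with weak peaks in sham. Of 12 monocyte and macrophage genes 4 gained a peak, Ccr2, the monocyte chemokine receptor, with 4.72, Arg1, arginase, with 1.74, Ms4a7 with 9.17 and Mrc1, the mannose receptor, with 3.67, and 1, F13a1, lost one (98.6th percentile). The net gains of both lists lay above the random range only by a tie with its upper bound. With strong peaks only, the monocyte and macrophage list gained 2 members and lay at the 91.1st percentile, inside the random range. Gpr65 had a fold of 44.0, Ly9, a lymphocyte adhesion receptor, 42.6, Sox14, a transcription factor, 38.9, Wdr70 32.3 and Tarbp2, a partner of Dicer, 23.5. Serpina3j (146) and Ppia (51.4) had higher folds and are uncertain, because both belong to families with near-identical copies or pseudogenes. H3c13, Mir2139 and Rilpl2 lay at places that sham listed under another name. Among the lost genes Zxda again had a sham fold of 529, followed by Grhl1, a transcription factor of epithelia, with 33.3, Olfr464 with 22.9, Mir129-2 with 21.9 and Iltifb, an interleukin-22 relative, with 21.0. The peak named Mir129-2 covered 447 bases in blocks from 94238276 to 94252172 on chromosome 2. It thus reached beyond a microRNA, and that name is uncertain. Slc5a3, Pnma1, Bbs12, Ctsa and Eif3m lay at places that day 3 listed under another name.

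At day 5 monocyte and macrophage genes, reactive astrocyte genes and cell death genes gained m6A peaks and none of their members lost one, while 3 JAK-STAT genes lost theirs. Of 12 monocyte and macrophage genes with a peak in any library, out of 18 on the list, all 12 had one at day 5 and 7 in sham (99.9th percentile). Ptprc was listed at day 5 alone, so it counts among the 12 only through that library. Ccr2 had a fold of 5.57, Arg1 2.72, Ms4a7 5.45 and Mrc1 2.86. Of 17 reactive astrocyte genes 4 gained a peak (98.1st percentile), including Cd44 with 3.28, Emp1, a membrane protein, with 7.91 and Cd109, a protein that binds transforming growth factor beta, with 2.93. Of 17 cell death genes 4 gained a peak (98.1st percentile), namely Bak1, a mitochondrial effector of apoptosis, with 7.03, Ripk3 and Mlkl, a kinase and its target in necroptosis, with 7.03 and 9.67, and Acsl4, a lipid enzyme of ferroptosis, with 2.49. The net gains of reactive astrocyte and cell death genes lay above the random range only by a tie with its upper bound. The Bak1 peak lay at a place sham listed under another name, and with strong peaks the cell death list gained 2 and lost 2 members. Of 26 JAK-STAT and SOCS genes 0 gained and 3 lost a peak, Tyk2, a Janus kinase, Stat4 and Stat5b, both STAT transcription factors, with sham folds of 7.62, 12.4 and 2.54 (2.13th percentile). All 3 of these sham peaks were weak, and with strong peaks none of the list was gained or lost. With strong peaks the monocyte and macrophage list gained 3 members and lay at the 96.1st percentile, inside the random range. With the same number of strong peaks from each library it lay at the 97.8th, above that range by a tie with its upper bound. Cd22, an inhibitory receptor of B cells and microglia, and Rgs1, a regulator of G protein signalling in leukocytes, each had a fold of 29.9, Chrm5, a muscarinic receptor, 29.0, Hcar2, a receptor for hydroxybutyrate, 26.4 and F7, coagulation factor VII, 22.9. Mfsd7a and Mir142hg, the host gene of a leukocyte microRNA, each had 21.1. Ube2v2, Psme2b and Gpat3 lay at places that sham listed under another name. The lost genes were led by Zxda and by Hnrnpa3, with a sham fold of 98.3, both uncertain because of near-identical copies. They further held Olfr464, Trim34b, Pou4f1 and Srrd with sham folds between 18.1 and 22.9, and D17H6S53E, Sgf29, Adamts3 and Lrfn2, whose places day 5 listed under another name.

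At day 7 the net gains of m6A peaks in lymphocyte genes, monocyte and macrophage genes and reactive astrocyte genes lay above the random range. That of monocyte and macrophage genes did so only by a tie with its upper bound. Of 15 genes on the lymphocyte list 6 had a peak in any library, all 6 of them at day 7 and 2 in sham (99.9th percentile). Cd8a and Gzmb were listed at day 7 alone, so they count among the 6 only through that library. The lymphocyte list had net gains of 1 gene at day 1 (Cd79b) and 2 at day 3 and day 5 (Lck and Cd79b), inside the random range. The gained members were Cd8a, a coreceptor of cytotoxic T cells, with a fold of 7.00, Lck, a T cell kinase, with 8.32, Cd79b, a subunit of the B cell receptor, with 17.5, and Gzmb, a granule protease, with 8.75. Only the Cd79b peak was strong, and with strong peaks the list lay at the 74.5th percentile. Of 12 monocyte and macrophage genes 3 gained a peak, Ccr2 with 17.5, Ms4a7 with 3.58 and Mrc1 with 7.00 (97.9th percentile, 97.3rd with strong peaks, just inside the random range, and 98.5th with the same number of strong peaks from each library, above it by a tie). Of 17 reactive astrocyte genes 5 gained a peak (99.8th percentile, 92.2nd with strong peaks), among them Hspb1 with 4.38, Cd44 with 2.69 and Emp1 with 3.21. Rnaset2a, a ribonuclease gene with a near-identical copy and therefore uncertain, had a fold of 84.0, Rgs1 73.5, Ly9 51.6, Rc3h1, an RNA-binding regulator of T cells, 27.1 and Mir142b 26.3. The peak named Mir142b covered 269 bases in blocks from 87755577 to 87757270 on chromosome 11 and ended at the same base as the day 5 Mir142hg peak. It thus reached beyond a microRNA, and that name is uncertain. Mir3098, Eng, Rilpl2, H3c13 and Mir5103 lay at places that sham listed under another name. Among the lost genes Tom1 had a sham fold of 36.2, mt-Nd3, a mitochondrial gene that is uncertain because of nuclear copies, 27.6, Olfr464 22.9 and Trim34b, which has a close copy, 19.1. Slc5a3, H2ax, Pnma1, Bbs12, Adamts3 and Alyref2 lay at places that day 7 listed under another name.

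Of the genes with a peak at all 4 days and none in sham, Rgs1 had the highest mean fold, 33.1 over the 4 injured lists, with its 3' UTR peak on chromosome 1 starting at 144244751 in each of them. Ly9 had a mean fold of 28.3, Rnaset2a 27.5, Gpr65 22.3, Wdr70 22.3, Sox14 19.3, Hcar2 17.6, Gpr35, a G protein-coupled receptor, 17.0 and Cd79b 16.9. H3c13, a histone gene with near-identical copies, had 25.3 at a place listed in sham under another name. The genes lost at all 4 days were led by Olfr464, an olfactory receptor gene (sham fold 22.9), Amer3 (14.7), Clrn2 (14.3) and F12, coagulation factor XII (13.3), and further held Flicr, Qrfprl, Cldn24, Mir135b, C1qtnf6 and Cyp4f16. Among those 10 lost genes only 3 had a strong peak in sham, and Amer3, Flicr and Mir135b lay at places listed after injury under another name. In all, 340 genes were gained at all 4 days and 381 lost. Setting another library against the remaining 4 in the same way gave 397 genes for day 1, 292 for day 3, 190 for day 5 and 221 for day 7 that the other 4 had and it lacked, so with all peaks sham did not give the highest number. Day 1 also gave more than sham with strong peaks (277 against 272), with a fold of at least 2 (330 against 269), with the same number of peaks from each library (349 against 319), and without genes that had a peak at the same place under another name, for all peaks (333 against 279) and for strong ones (229 against 224). Only with a strong peak in the lists that have the gene and no peak in the other did sham give the most, 47 against 27 to 34. On the lost side, sham alone had a peak in 381 genes, day 1 in 298, day 3 in 267, day 5 in 563 and day 7 in 387.

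Strong peaks set 4 of the fixed gene lists apart from random lists at 3 or more days, those of reactive astrocytes, complement, phagocytic myeloid cells and cytokines. Phagocytic myeloid cells at day 1 and cytokines at day 3 stood apart only by a tie with the upper bound of the random range. With all peaks, complement lay above the random range at no day, and phagocytic myeloid cells and cytokines at 1 day each. With all peaks phagocytic myeloid genes gained 3, 6, 6 and 6 members and lost 2, 2, 3 and 4 at days 1, 3, 5 and 7, the losses at day 7 being Trem2, Cd68, Cd9 and Axl, and cytokines gained 7, 3, 4 and 3 and lost 2, 2, 0 and 2. Of 16 reactive astrocyte genes with a strong peak in any library, out of 22 on the list, 7 had one in sham, 16 at day 1, 12 at day 3, 12 at day 5 and 10 at day 7. None lost a strong peak, and the list lay above the central 95% of random lists at day 1 (100th percentile), day 3 (99.9th) and day 5 but not at day 7 (92.2nd). Steap4, Hspb1 and Emp1 had a strong peak at day 1 alone, so they count among the 16 only through that library. Vim, an intermediate filament protein, had a weak peak in sham (fold 2.86, log10 p -3.41) and a strong one at every day, with a log10 p of -35.0 at day 5. Of 11 complement genes 6 had a strong peak in sham, 9 at day 1 and 10 at each later day (above the central 95% at each day, at the 99.9th percentile at day 3 and the 99.8th at day 7). C5ar1, the receptor for the C5a fragment, had a fold of 15.2 and a log10 p of -3.71 in sham and a log10 p of -35.2 at day 1, and Serping1, the C1 inhibitor, had a weak peak in sham and strong ones at every day. The p-values of Vim and C5ar1 come from lists of unknown depth and do not measure a change in methylation. Of 12 phagocytic myeloid genes 5 had a strong peak in sham, 8 at day 1, 10 at day 3, 11 at day 5 and 8 at day 7 (98.1st, 99.97th, 100th and 96.5th percentiles), with Apoe, a lipid carrier, strong from day 3 on and Spp1 strong at all 4 days. Of 7 cytokines 2 had a strong peak in sham, 6 at day 1, 5 at day 3, 6 at day 5 and 4 at day 7 (99.9th, 98.6th, 99.6th and 89.0th percentiles), with Lif, a cytokine of the interleukin-6 family, with no peak listed in sham and strong ones at all 4 days. With the same number of strong peaks from each library, Lif was no longer gained at day 5 and day 7. The NF-kB and toll-like receptor list was above the random range at day 5, with 20 of 21 genes against 13 in sham (99.1st percentile), and at day 7 with 19 (98.8th). With the same number of strong peaks from each library, cytokines at day 5 (95.2nd percentile) and the NF-kB and toll-like receptor list at day 7 (96.5th) lay inside the random range. Phagocytic myeloid genes at day 7 (98.3rd) and heat shock and hypoxia genes at day 5 (98.2nd) lay above it, each by a tie with its upper bound. Of the heat shock and hypoxia genes gained at day 5, Hspa1a, Hmox1 and Ldha, the first lay at a place that sham listed under another name.

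**Figure D3:**
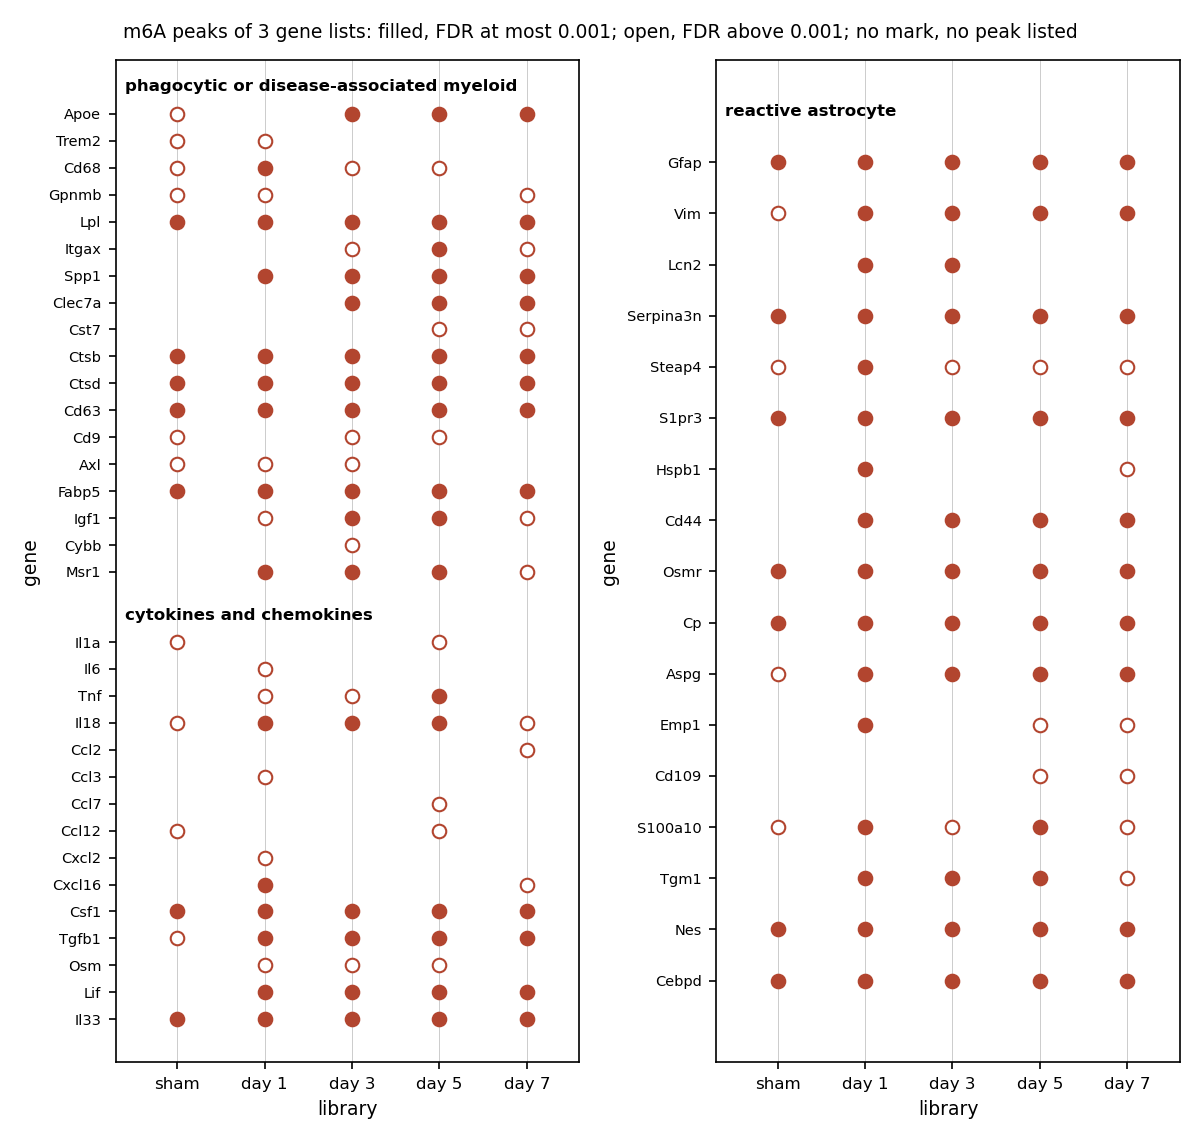
m6A peaks of the members of 3 gene lists (vertical axis) in the 5 libraries (horizontal axis), filled where the best peak has an FDR of at most 0.001, open where the FDR is above 0.001 and blank where no peak is listed. Reactive astrocyte genes have 7 filled marks in sham and 16 at day 1, and phagocytic myeloid genes 5 in sham and 11 at day 5.

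Several lists had a peak for every member in sham and could show no gain with all peaks. Peaks were listed for all 14 homeostatic astrocyte genes, 16 oligodendrocyte and myelin genes, 10 oligodendrocyte precursor genes, 17 endothelial and pericyte genes and 21 immediate early genes in every library. Strong peaks numbered 14 of 16 endothelial and pericyte genes in sham, 15 at day 1 and day 3, 13 at day 5 and 14 at day 7, and 12 of 14 homeostatic astrocyte genes in sham and day 1 and 14 at each later day, with percentiles inside the random range. Homeostatic microglia genes with a peak numbered 17 of 18 in sham, day 1, day 3 and day 7 and 18 at day 5, and 16 had a strong peak in every library. Neuronal genes with a peak numbered 31 of 32 in sham, 29 at day 1 and 32 at each later day. Neutrophil genes with a peak numbered 2 of 8 in sham, 5 at day 1, 4 at day 3, 5 at day 5 and 4 at day 7, and the highest percentile was 95.9 at day 1. Interferon response genes numbered 17 of 20 in sham and 17 or 18 after injury, extracellular matrix and scar genes 16 of 19 in sham and 16 to 18 after injury, heat shock and hypoxia genes 13 of 15 in sham and 13 or 14 after injury, and cell cycle genes 10 of 16 in sham, 10 at day 1, 9 at day 3, 12 at day 5 and 14 at day 7. None of these 4 lists left the central 95% of random lists with all peaks. With all peaks, JAK-STAT and SOCS genes numbered 25 of 26 in sham and 22 to 24 after injury, NF-kB and toll-like receptor genes 21 of 24 in sham and 20 to 23 after injury, and complement genes 10 of 12 in sham and 10 to 12 after injury. Of 6 red blood cell genes 1 had a peak, at day 7 alone.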

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

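The alternatives on the strand, on gene names, on a strong peak against no peak at all and on the same number of strong peaks were chosen after seeing the data, and the others were planned. No paired analysis was possible because each group had 1 IP library and no result came from a test. The comparisons meant for input level (for gained and lost genes and for the level itself), on the enrichment change at shared peaks and on the peak per gene and the centring of gene lists were not run, since they need reads or input levels that were not analysed here, and what depth limits cannot be stated for the same reason. For all values given in this part the cause was not tested, except where a stricter threshold leaves fewer peaks by construction. A fold of at least 2 left the peak numbers within 1.5 times, and an FDR of at most 0.001 left 18083 peaks in sham, 18227 at day 1, 18517 at day 3, 19599 at day 5 and 19147 at day 7. The 3' UTR share went, in the same order, to 59.0%, 59.1%, 59.1%, 58.6% and 58.0% with that FDR and to 50.1%, 50.4%, 50.7%, 49.4% and 49.2% with a fold of at least 2. The share of peaks that a sham peak overlaps at days 1, 3, 5 and 7 was 82.6%, 83.4%, 78.1% and 80.8% with 1 base, 71.2%, 72.4%, 67.2% and 69.8% with 50% of both peaks, 87.8%, 87.8%, 83.4% and 85.8% with strong peaks in both lists, 80.7%, 81.5%, 79.96% and 80.4% with the same number of peaks, and 80.1%, 80.9%, 75.3% and 78.05% on the same strand of the annotated gene. The day 5 list is the longest, so the same number of peaks takes away its surplus by construction. With strong peaks in every list the lost genes numbered 983 at day 1, 806 at day 3 and 765 at day 7, and those lost at all 4 days 220. A strong peak against no peak at all left 285 gained and 225 lost genes at day 1, 278 and 221 at day 3, 383 and 194 at day 5, 307 and 204 at day 7, and 47 and 35 at all 4 days. Strong peaks with no strong peak at the same place under another name left 821 gained and 827 lost at day 1, 652 lost at day 3, 1241 gained and 595 lost at day 5, 597 lost at day 7, and 224 gained and 166 lost at all 4 days. Leaving out each injured library in turn gave 420 to 501 genes gained and 464 to 529 lost in the remaining 3. The gene lists above the central 95% of random lists numbered 2, 2, 3 and 3 with all peaks, and with strong peaks 4, 4, 5 and 2 at days 1, 3, 5 and 7, and 4, 4, 6 and 3 with the same number of strong peaks. The net gain of cell death genes at day 5, 4 with all peaks, was -1 with the same number of strong peaks. Of the 96 net gains of gene lists, 29 stayed within 1.5 times with strong peaks and 7 turned their sign, and with the same number of strong peaks 27 stayed within 1.5 times and 9 turned their sign. Those that turned were of the JAK-STAT, NF-kB, extracellular matrix, cell cycle, m6A reader and cell death lists, and cell death at day 5 was the only one of them outside the central 95% of random lists with all peaks.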

Other observations

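Genes with a strong peak at all 4 days and none in sham numbered 272, and among 296 pathways named in the files none stood out. In this direction no pathway count was matched by as few as 10 of 10000 random lists, where 0.296 pathways would be by chance. The highest was xenobiotic metabolism by cytochrome P450, with 4 of its 16 genes, Cyp1b1, Ephx1, Gsta4 and Gstp1, against a mean of 0.631 in random lists, 24 of which held as many. Chemokine signalling held 7 of 109 genes, a number that 91 of 10000 random lists reached.

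The tests on the number of genes gained, on weak peaks, on gene names among gained genes and on fold steps were chosen only after the result was seen. Those on the 4 gene lists with strong peaks use alternatives that were also added after seeing the data, and only what each outcome would mean was written before its value was computed.

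Genes gained at all 4 days, 340 with all peaks and 272 with strong peaks, could be a sign of injury or of the sham library. The 5 libraries are too few for a share of splits under 0.05: with all peaks 2 of the 5, sham included, gave at least 340 genes, the highest other being 397 for day 1, and with strong peaks 2 of the 5 gave at least 272, the highest other being 277 for day 1. Against sham at single days, 78.3% to 80.03% of gained genes had no strong peak, compared with 17.3% to 19.0% of genes listed in both libraries, so peaks near the detection limit are a candidate source of most gains, such as those of Il6 and Ccl3 at day 1. A true gain could also give a weak peak, so these shares cannot tell the sources apart. Gene names that switch between overlapping genes cannot be the main source of all gains, since at most 17.0% had a sham peak at the same place under another name. Among genes with a strong peak and no sham peak under their name that share was 39.7% to 50.4%, compared with 5.21% to 5.51% of shared genes, so a switched name may stand behind many of these, as for Ccdc71 and Tma7.

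Reactive astrocyte, complement, phagocytic myeloid and cytokine genes gained strong peaks, 19 of the 46 with a strong peak in any library at day 1, 17 at day 3, 19 at day 5 and 12 at day 7, with 0 lost, and the lists were picked because of this gain. With all peaks, phagocytic myeloid genes lost 2 to 4 members at each day and cytokines 2 at each day but day 5. With the same number of strong peaks from each library the net gains were 19, 17, 17 and 10, so a surplus of strong peaks accounts for little of the gain. At day 1 this setting took away few peaks, from 18227 to 18083. These net gains lay above the central 95% of random lists at each day, which adds no support, since the lists were picked for nearly the same gain. Switched gene names do not account for the gain, since none of the gained members had a strong sham peak at the same place under another name and the lowest net gain stayed at 12. More transcript or more cells of these types and more methylation per transcript cannot be told apart, because input levels were not analysed here. Up to 9 gained members at 1 day had a weaker peak in sham, as Vim, C5ar1 and Serping1 did, which is consistent with the same sites being read from fewer transcripts but would also be seen with less methylation.

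Fold enrichment at weak peaks came in whole steps, which bears on the Socs3 values. Of peaks with a fold of 6 to 10 and a log10 p above -3.5, on chromosomes not used to find the step, at least 95.7% in each list lay within rounding of a whole multiple, compared with 1.07% to 1.39% for an even spread. This is what folds made from whole reads over 1 fixed input value would give, and may mean that input at such peaks was at a floor. The sham Socs3 fold of 27.6 is 29.0 steps of 0.953, whole within rounding, while the injured folds, 18.7, 27.1, 14.3 and 12.1 steps, are not whole. The sham fold could therefore be set by a floor in the input, and whether Socs3 methylation differs between sham and injury stays open, since 12.02% of folds spread evenly would also be whole within that rounding. Genes named for the highest folds were not set against the steps, so a floor in the input could also shape those rankings.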
